A study of Mus musculus with 8 samples.

How the data were processed

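RNA from whole blood of 8 mice, 4 control and 4 hypoxic, was hybridized to 1 Affymetrix array per mouse. Per the labels' protocols, 100 µl of blood drawn from the vena cava was extracted with a blood RNA kit, and the RNA was amplified with an oligo(dT)-primed one-cycle kit and labelled with biotin. No globin reduction step and no batch or scan date is given in the sources used here. Groups were taken from the sample titles, which give each mouse a number of its own.

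A table of expression values with 45101 probe sets for the 8 arrays and a table of the authors' own comparison with 38206 probe sets were deposited. Per the submitters' processing notes, GCRMA and Partek were used, and their versions are not given in the sources used here. GCRMA corrects each probe for background by its sequence, normalizes the arrays and summarises the probes of a probe set on the log2 scale. Because it pulls unexpressed probe sets to a floor, changes of dim probe sets are compressed and changes between the floor and a measured level are uncertain. The second table is a significance analysis of microarrays (SAM), per the file headers, and holds for each listed probe set the authors' score, the log2 difference of group means, a denominator, a linear fold ratio of hypoxic over control, and a q-value in percent.

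The deposited expression values were not usable as listed. The decimal point of the log2 values had been lost, so that 5.63828 is listed as 563.828 and 10.8836 as 108.836, and values with no more than 2 decimals had been turned into spreadsheet day numbers, so that 6.19 is listed as 43.617. Every possible reading of each listed value was formed, and for each probe set of the authors' SAM table the reading was kept that gave the deposited log2 difference of means to within 5e-06. Exactly 1 reading did so for 38201 probe sets and several did for 5, for which the reading with the least spread was taken. Of the 305648 values recovered in this way, 330 had been day numbers. The recovered values were then checked against 2 deposited columns that had not been used to find them. The linear fold ratios differed by at most 1.6e-06 in relative terms, and the deposited denominator minus the recomputed standard error was 0.0784 for every probe set, with a range of 6.2e-07. The 6895 probe sets outside the SAM table were read from the other arrays of the same probe set alone. On simulated values damaged in the same way, 100.00% were put back with the log2 difference and 98.79% from the other arrays alone. The second share started from values that the same reading had given, so it does not measure how often that reading is right. Every probe set of the authors' table had a log2 value above 3 on at least 3 arrays, and no probe set outside it did on more than 2.

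The 64 control probe sets of the array (identifiers starting with AFFX) were left out of the main fit. Probe sets with a log2 value above 4 on at least 4 of the 8 arrays were tested, 29231 in all, with limma (version 3.58.1, lmFit and eBayes, R 4.3.3), with group as the only term, two-sided, and a Benjamini-Hochberg adjusted p under 0.05 as the threshold. Exact permutation tests used all 70 assignments of 4 of 8 mice, and the smallest two-sided p they can give is 0.0286. On simulated arrays of 29231 probe sets with the spread of these arrays and 200 changed probe sets, limma recovered 92.4% of 4-fold, 62.7% of 2-fold and 7.5% of 1.5-fold changes in the hypoxic versus control comparison, with 8 false calls. In the data 9114 probe sets passed, and the Benjamini-Hochberg limit is looser where more probe sets change. These shares and false calls therefore do not carry over to the data. The number of arrays limits the precision of every value. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for the recovery of the values and the plots.

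No table used here pairs the array's probe sets with genes. The gene lists fixed before the data were examined (blood cell types, heme synthesis, iron, glycolysis, hypoxia targets and others) were therefore not tested as lists. Genes are named only where the identifier of a control probe set carries the name, which was decided after the files were seen, and these were tested in the same limma fit with the control probe sets kept. The planned rule for named genes asked for the largest changes past the threshold with no overlap between groups, and 2 probe sets per direction are given by identifier. Alternatives for the filter, the variance model, the scaling, the array weights, a block for the replicate number, the test (SAM with all 35 splits of the mice), the threshold and each mouse left out were also run. The same-numbered mice of the 2 groups are different animals, and their deviations from the group means had correlations of -0.11, -0.06, -0.10 and 0.06.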

Results

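Gene expression was measured in whole blood of mice to compare animals exposed to falling oxygen on an expedition to Mount Everest with animals kept at room conditions in Kathmandu. Oxygen was lowered from 21% to about 7% for the hypoxic mice, and blood was drawn after 15 days. There were 4 control and 4 hypoxic mice, with 1 array per mouse. The groups also differed in whatever else the expedition brought with it, which this design cannot separate from oxygen. Whole blood mixes many cell types, and the cell type lists could not be tested. A rise or fall given below may therefore lie in the mix of cells, within cells, or in both, which these values cannot tell apart. Values are GCRMA log2 expression with the SD over 4 mice, unless stated otherwise. The labels number the mice separately and do not say whether they came from more than 1 cage or shipment.

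The transferrin receptor (Tfrc), which takes up transferrin-bound iron and is abundant on red cell precursors, rose in the blood of the hypoxic mice. At the 3' probe set of the transcript its level went from 5.36 ± 0.40 in controls to 8.47 ± 0.44 in hypoxic mice, a change of 3.11 ± 0.24 (SE) on the log2 scale or 8.64-fold (adjusted p = 1.42e-05, limma). The 5' probe set rose by 1.37 ± 0.22 (SE), from 3.67 ± 0.12 to 5.04 ± 0.50 (adjusted p = 0.000971, limma). Its control values of 3.53 to 3.83 lie under the highest mean of a bacterial control probe set, 4.31, and above the next highest, 3.30. They also lie under the filter level of 4, so the size of this rise is uncertain. With values under 4 set to 4 the rise was 1.04 (adjusted p = 0.00457, limma). The middle probe set rose by 0.92 ± 0.26 (SE), from 5.63 ± 0.27 to 6.55 ± 0.60 (adjusted p = 0.0208, limma). In all 3 probe sets every hypoxic mouse lay above every control mouse. The middle probe set is the least firm of the 3, since its adjusted p in limma was 0.0579 without control replicate 4 and 0.0907 in a linear model without moderation. Tfrc was the only identified member of 3 of the lists fixed beforehand, those for erythroid cells, iron handling and hypoxia targets outside glycolysis, so these lists could not be tested.

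Pyruvate carboxylase (Pcx), the mitochondrial enzyme that makes oxaloacetate from pyruvate, rose at 3 of its 4 probe sets. The 3' probe set went from 5.57 ± 0.29 to 7.03 ± 0.19, a change of 1.46 ± 0.17 (SE) or 2.75-fold (adjusted p = 0.000152, limma). The probe sets of the middle of the transcript rose by 0.55 ± 0.14 and 0.63 ± 0.14 (SE), with adjusted p of 0.0145 and 0.00612 in limma. Both of these changes lie under 0.68, the largest change of a bacterial control probe set, for which mouse RNA holds no target, and the second was 0.42 with values under 4 set to 4. At the 5' probe set the change was 0.34 ± 0.14 (SE) and did not pass the threshold (adjusted p = 0.0861, limma), although all 4 hypoxic mice lay above all 4 controls there too. With arrays centred on their median it did pass (0.41, adjusted p = 0.0438, limma).

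**Figure D1:**
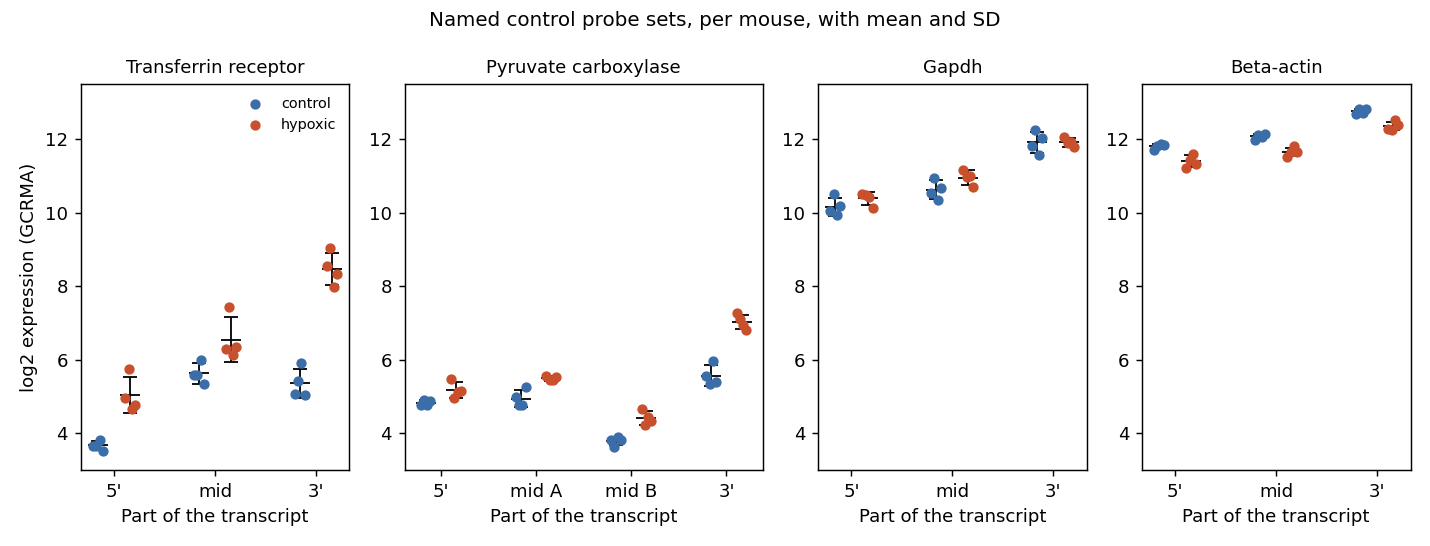
Log2 expression of the control probe sets named for 4 mouse genes, by part of the transcript, with 1 point per mouse (4 control, 4 hypoxic) and bars for the mean and SD. The hypoxic mice lie above the controls at every transferrin receptor and pyruvate carboxylase probe set, most of all at the 3' end (8.64-fold and 2.75-fold), overlap them for Gapdh, and lie below them for beta-actin.

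Glyceraldehyde-3-phosphate dehydrogenase (Gapdh), a glycolytic enzyme and the only identified member of the glycolysis list, did not pass the threshold at any of its 3 probe sets. Its 3' probe set was at 11.91 ± 0.28 in controls and 11.91 ± 0.12 in hypoxic mice, a difference of 0.01 with a 95% interval from -0.34 to 0.35 (adjusted p = 0.982, limma). The sign of that difference turned under renewed quantile normalization (-0.07) and under array weights (-0.02). The Gapdh middle and 5' probe sets differed by 0.33 ± 0.16 and 0.23 ± 0.16 (SE), with adjusted p of 0.146 and 0.282 in limma.

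Beta-actin (Actb), the main cytoskeletal actin of blood cells, fell at all 3 of its probe sets by similar amounts. The 3' probe set fell by 0.39 ± 0.12 (SE), from 12.75 ± 0.07 to 12.35 ± 0.11 (adjusted p = 0.0325, limma), the middle one by 0.42 ± 0.13 (adjusted p = 0.0256, limma) and the 5' one by 0.40 ± 0.13 (adjusted p = 0.0374, limma). No beta-actin value overlapped between groups. The direction held under every scaling tried, but the adjusted p in limma lay above 0.05 when arrays were centred on their median (0.0667 at the 3' probe set, with a fall of 0.32) or on their spike-ins (0.0584, a scaling added after the data were seen). At the 3' probe set it lay between 0.0526 and 0.0795 when any 1 mouse other than hypoxic replicate 3 was left out.

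The probe set named for the B1 repeat, a short interspersed element found in many mouse transcripts, fell by 0.70 ± 0.15 (SE), from 11.49 ± 0.21 to 10.78 ± 0.15 (adjusted p = 0.00482, limma). The brighter of the B2 repeat probe sets differed by -0.33 ± 0.13 (SE) and did not pass the threshold (adjusted p = 0.0668, limma). Its groups did not overlap, and it did pass with a trended and robust variance (0.025), with the stricter filter (0.0467), in a linear model without moderation (0.0251) and in SAM (0.0384). The dimmer one differed by -0.16 ± 0.16 (SE) with an adjusted p of 0.483 in limma. Of the 18S ribosomal RNA probe sets, the 3' one rose by 0.97 ± 0.26 (SE) with an adjusted p of 0.0157 in limma, and 0.0783 in a linear model without moderation. The groups overlapped at this 3' probe set, with control replicate 3 at 7.12 and hypoxic replicate 1 at 6.86 (exact permutation p = 0.0571). The middle 18S probe set differed by -0.19 ± 0.16 (SE, adjusted p = 0.389, limma) and the 5' one by 0.19 ± 0.33 (SE, adjusted p = 0.695, limma). The 5' difference was 0.57 without control replicate 3 and 0.00 without control replicate 2. The 3' minus 5' difference of 18S rose by 0.78 ± 0.15 (SE), that of Tfrc by 1.74 ± 0.17 and that of Pcx by 1.12 ± 0.20, while those of beta-actin and Gapdh changed by 0.01 ± 0.07 and -0.23 ± 0.06.

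Across the array, the difference between groups was larger than that between mice of a group. The first principal component held 59.3% of the variance, with the controls between -63.3 and -41.7 and the hypoxic mice between 35.2 and 65. Arrays of the same group had correlations across probe sets of 0.956 to 0.979, and arrays of different groups 0.907 to 0.944. No 2 arrays had identical values at more than 0.29% of probe sets, so none appears to be deposited more than once.

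**Figure D2:**
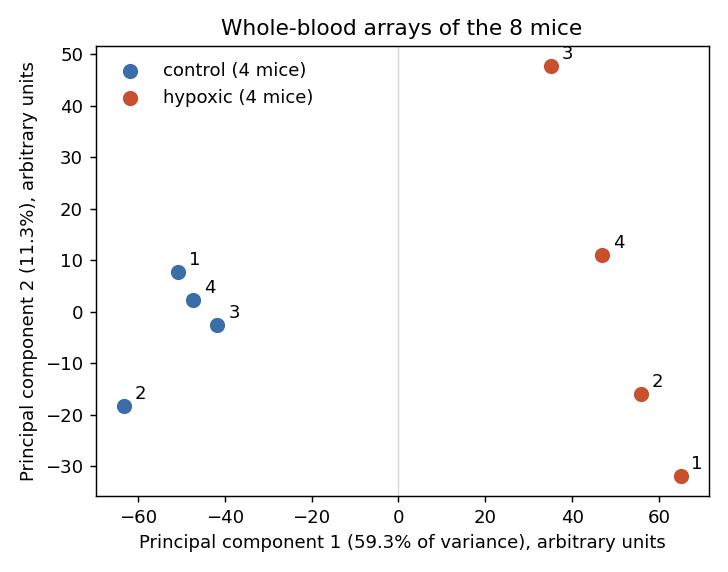
First and second principal components of the 29231 tested probe sets (arbitrary units), with 1 point per mouse labelled by its replicate number. The first component, with 59.3% of the variance, parts the 4 control from the 4 hypoxic mice, and the second, with 11.3%, spreads the hypoxic mice.

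Of 29231 probe sets tested, 9114 passed the threshold in limma, of which 3614 rose and 5500 fell, and 20117 did not pass. With each array centred on its median, 4631 rose and 4458 fell, and with each array centred on its spike-ins 3087 rose and 4656 fell, so the excess of falls was absent under the first scaling and present under the second. Among changes of at least 1.5-fold falls outnumbered rises (4208 against 2477), while 1271 probe sets rose and 1086 fell at least 2-fold, and 258 rose and 24 fell at least 4-fold. In 31.9% of tested probe sets the mice of one group all lay on one side of the other group, where chance alone gives 2.86%. The 2 largest rises in this fit were those of probe set 1424877_a_at, from 7.33 ± 0.52 to 11.44 ± 0.29 or 17.3-fold (adjusted p = 4.61e-06, limma), and of 1433720_s_at, from 6.13 ± 0.50 to 10.15 ± 0.18 or 16.3-fold (adjusted p = 3.58e-06, limma). The 2 largest falls in this fit were those of 1456182_x_at, from 8.38 ± 0.58 to 5.11 ± 1.85 (adjusted p = 0.00556, limma), where the hypoxic mice differed widely and the adjusted p was 0.0591 in a linear model without moderation, and of 1421499_a_at, from 8.74 ± 0.61 to 5.55 ± 0.15 or 9.17-fold (adjusted p = 1.63e-05, limma). Their order is not firm, since 1456182_x_at changed less than 1421499_a_at with array weights (-2.92 against -3.21), with the floor at 4 (-3.09 against -3.20), and without control replicate 1 or 2 or hypoxic replicate 1 or 3 (-2.70 against -3.25 without hypoxic replicate 1). Without hypoxic replicate 4, at 7.46 against 3.41 to 5.70 in the other hypoxic mice, the change of 1456182_x_at was -4.05. The order of the 2 rises turned without control replicate 4 (4.00 against 4.12) and without hypoxic replicate 1 (3.97 against 4.08).

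The direction of change differed with the level of expression. Of probe sets with a mean log2 level of 6 to 8, 2401 fell and 975 rose, with a median change of -0.30 over the 7206 tested. Under 6, 2293 fell and 1884 rose, with a median change of 0.00, and from 8 to 10, 624 fell and 538 rose, with a median of -0.11. Of the brightest, with a mean of 10 or more, 182 fell and 217 rose of 741 tested, with a median change of 0.07. The share that passed the threshold was 21.3% for means under 6, 46.8% for 6 to 8, 70.2% for 8 to 10 and 53.8% for 10 or more. The 27 bacterial control probe sets, for which mouse RNA holds no target and 22 of which were read from the other arrays alone, averaged 2.19 ± 0.04 per array in controls and 2.50 ± 0.08 in hypoxic mice (exact permutation test, two-sided, p = 0.0286, n = 4 per group, the smallest p this design can give). The 18 probe sets for RNA spiked in at hybridization averaged 12.12 ± 0.03 and 12.11 ± 0.15 (exact permutation test, two-sided, p = 0.886, n = 4 per group).

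**Figure D3:**
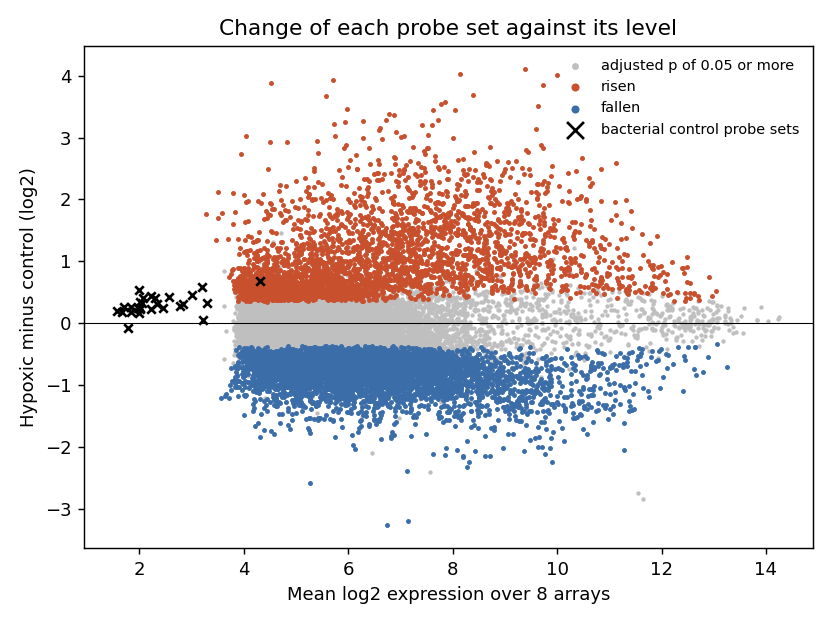
Hypoxic minus control log2 difference of each tested probe set against its mean log2 level over the 8 arrays, coloured by whether it rose (3614), fell (5500) or did not pass an adjusted p of 0.05 in limma. Crosses mark the 27 bacterial control probe sets, 26 of which lie above 0, the highest at 0.68.

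In the authors' deposited table, 13934 of 38206 listed probe sets had a q-value under 5%, 6294 with a higher and 7640 with a lower mean in the hypoxic mice, and 1084 had a q-value of 0. All 9114 probe sets called in limma were among them, and 2849 further tested probe sets were called in the authors' deposited table alone. Each shared call had the same direction, but this was forced. The values had been read so as to give the deposited difference of means. The overlap compares tests on the same values and is no independent check of them. In the authors' deposited table the transferrin receptor 3' probe set had a fold of 8.68 and a q-value of 0%, and the Gapdh 3' probe set a fold of 0.992 and a q-value of 42.5%. These folds come from the same arrays, so they are no independent measurement of the changes given above.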

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

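Leaving out each mouse in turn was planned, and the other tests in this part were chosen after the values they explain had been seen. In 68 groups of 4 mice, 4 values stood apart from the other 3 of their group by Dixon's criterion, where about 3.4 are expected by chance.

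Control replicate 1 had 56 probe sets that were bright on its array alone, at a log2 value of at least 4 and at least 2 above the next array, against 1 to 9 on the other control arrays and 0 or 1 on each hypoxic array. Of the 56, 44 reached a log2 value of 6 and the brightest 11.45, up to 7.45 above the next array. If the decimal point had been read wrongly, the recovered values would not give the authors' deposited fold, which was not used to read them, and they give it for all 38 of the 56 that the authors' table lists, which argues against damage to the table as the source for these 38. This check replaced an earlier one that values read from the rest of their row could hardly fail, and the agreement of the fold over the whole authors' table was known when it was chosen. The other 18 were read from the row alone and have no such check. The count of changed probe sets was 7033 without control replicate 1 and 9114 with it, and 6872 to 9315 when each mouse was left out in turn. What these probe sets measure was not tested, since their genes are unnamed here, and RNA from another tissue, a state of that mouse and a fault of the array all stay open.

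The middle probe set of the transferrin receptor was at 7.44 in hypoxic replicate 2 against 6.13 to 6.34 in the other hypoxic mice. Without hypoxic replicate 2 its rise was 0.63 (adjusted p = 0.0236, limma) against 0.92 with all mice. The smaller value lies under 0.68, the largest bacterial control change. Probe set 1433720_s_at was at 5.39 in control replicate 2 against 6.27 to 6.43 in the other controls. The 3' minus 5' difference of beta-actin was 0.85 in control replicate 3 against 0.98 to 1.00 in the other controls.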

How the results depend on the processing

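Centring arrays on their spike-ins, the authors' filter, keeping the control probe sets and a limit set by the bacterial controls were added after the data were examined, and the other choices were fixed before. The counts of changed probe sets, of rises, of falls and of calls shared with the authors' deposited table stayed within 1.5 times the main values (9114, 3614, 5500 and 9114) under most settings, and every call shared between a setting and the main analysis had the same direction. The exceptions were the stricter filter, which tests 10210 probe sets and gave 5809 calls, 1978 of them rises, with 5809 shared with the authors' table; the linear model without moderation, with 3607 falls (the cause was not tested); and an adjusted p under 0.01, with 4617 calls, 1954 rises and 2663 falls. Requiring a change beyond the largest bacterial control change gave 5398 calls, 2053 rises and 3345 falls. Leaving out each mouse in turn gave 6872 to 9315 calls. With the replicate number as a block (replicate block) there were 7764 calls, and all 3 beta-actin probe sets lost theirs. Of the 4 controls, 1 correlated best with the hypoxic mouse of its own number. No pairing by number was seen, and 4 pairs are too few to exclude one. The share of rises among calls was 39.7% in the main analysis, 39.9% with arrays centred on their spike-ins, 48.2% after renewed quantile normalization and 51% with arrays centred on their median. Gapdh at its 3' probe set, not called in any setting, turned sign to -0.07 with renewed quantile normalization, to -0.02 with array weights, and lay between -0.11 and 0.11 when each mouse was left out in turn (the cause was not tested). Over all settings the transferrin receptor 3' change lay between 2.92 and 3.29 and the pyruvate carboxylase 3' change between 1.38 and 1.60. Not run were the gene list tests and the fit with 1 probe set per gene, for want of gene names, and the fit on values of the SAM table, which holds none per mouse. Signal near the GCRMA floor limits what can be said of dim probe sets.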

Other observations

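The splits of the mice were planned before the data were examined, and the other tests in this part were chosen after the values had been seen. Of the 35 splits of the 8 mice into 4 and 4, only 1, the real one, gave as many changed probe sets, with 9114 against at most 1 in any other. Every other split mixes control and hypoxic mice, which widens the spread within its groups and lowers its count. The share of splits cannot fall below 1 in 35, so chance is made less likely and is not excluded.

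The rise of the transferrin receptor and of pyruvate carboxylase depended on the part of the transcript. For the transferrin receptor the middle probe set rose least (0.92, against 1.37 at the 5' and 3.11 at the 3' one), so the rise did not climb steadily from 5' to 3'. For pyruvate carboxylase the middle probe sets (0.55 and 0.63) lay between the 5' one (0.34) and the 3' one (1.46). The 3' minus 5' difference of the transferrin receptor went from 1.69 ± 0.30 to 3.43 ± 0.16 and that of pyruvate carboxylase from 0.74 ± 0.35 to 1.86 ± 0.20 (SD, n = 4 per group, exact permutation p = 0.0286 each and 0.0357 adjusted over 5 transcripts), where the transferrin receptor 5' values of the controls, 3.53 to 3.83, lie near the floor. More degraded RNA in the hypoxic mice would raise the difference for other mRNAs too. The difference changed by 0.01 for beta-actin and by -0.23 for Gapdh, but rose by 0.78 for 18S (from -0.91 ± 0.26 to -0.13 ± 0.14). Since 18S ribosomal RNA has no poly(A) tail for oligo(dT) to prime on, its difference is no sure gauge of mRNA degradation. The change of Gapdh, in the opposite direction, and that of 18S reached the same exact permutation p of 0.0286 (0.0357 adjusted), the smallest this design can give. For beta-actin p was 1. Beta-actin and Gapdh argue against a degradation that reaches all mRNAs alike. They are only 2 bright transcripts, so degradation of the transferrin receptor and pyruvate carboxylase mRNAs stays open. Compression of dim values by the background correction stays open too, since levels of different probe sets cannot be compared on an array, and a difference in the transcript forms made was not tested.

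Probe sets near the floor lay higher on the hypoxic arrays. The bacterial control probe sets, at mean levels of 1.58 to 4.31, were higher by 0.30 on average. Their array means were 2.19 ± 0.04 in controls and 2.50 ± 0.08 in hypoxic mice (SD, n = 4 per group). The mouse probe sets nearest to them in level were higher by a median of 0.13 on average. This did not extend to all dim probe sets, since those tested with a mean under 6 had a median change of 0.00, with 2293 falls and 1884 rises. The difference near the floor is consistent with a higher background on the hypoxic arrays as the source of small rises near the floor. Of the rises called, 2053 exceeded 0.68, the largest bacterial control change. Of the 258 rises of at least 4-fold, 46 had a mean level under 6, and the rest lay above the bacterial range. The size of these 4-fold rises, each beyond 0.68, argues against a background shift like that of the bacterial controls as the source of most of them. How far background reaches into smaller rises was not tested, and the biological difference between the groups stays open as an explanation. Batch and scan date are not given, so a shared day for each group cannot be examined. The long numbers that end the sample titles are all lower for the hypoxic mice than for the controls. What these numbers count is not said, so an order of handling that follows group stays possible.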
